A study of Mus musculus with 6 samples.

How the data were processed

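RNA of F4/80-selected liver cells was measured in 6 libraries, 3 from WT and 3 from KO mice, all given CCl4. Groups and replicate numbers were taken from the labels. The submitters' processing notes list bcl2fastq 2.17, STAR 2.4.0k, SAMtools, HTSeq 0.5.3 and DESeq 1.8.3 and the build GRCm38.p4, without roles or order. The annotation release, the counting options, including the strand setting, and the treatment of reads that match several places are not given in the sources used here. Genes that overlap on opposite strands could therefore share reads.

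Each deposited table holds 1 library with a signal for each of 79382 Ensembl transcripts, which the file header names normalised counts. Per the file headers and the values, this signal is a read count that the authors divided by 1 factor per library. In each library 100% of the values were whole multiples of the smallest nonzero value, within a tolerance of 0.001, so whole reads could be recovered. Many isoforms of a gene held nearly equal values. The 2 highest transcripts had means within 5% of each other in 5986 of the 12326 genes with more than 1 transcript. The recovered reads over all transcripts were 2.27 to 2.65 times those over 1 transcript per gene. The transcript with the highest mean over the 6 libraries was therefore kept for each gene. Transcripts were matched to genes, symbols and coordinates in the GENCODE annotation of GRCm38, which matched 78332 transcripts and 23394 genes. The 1050 transcripts that did not match, 1.03% to 1.32% of the reads of a library, were not analysed here.

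The test fixed before the data were examined was edgeR's quasi-likelihood test on counts. Because the deposited values were scaled, the main test became limma with a trended prior on log2(value + 1), with the authors' factors and genotype as the only term. Fold changes are on this scale, which understates changes of low genes. Genes were kept by filterByExpr on the recovered reads, which left 15619 genes, and 7775 were not tested. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. edgeR's quasi-likelihood test with TMM factors on the recovered reads was run as an added alternative, on values that came out whole for 100% of transcripts, and called 282 genes. Gene lists were written from general knowledge before the data were examined: 27 functional lists and 15 marker lists, of 822 entries in all, of which 799 were tested. The list test fixed before the data were examined was camera on voom log2-CPM values with TMM factors. The main list test became camera on the log2 values of the gene test, with the preset inter-gene correlation of 0.01. Lists with at least 4 measured genes were tested and adjusted over 42 lists. With voom on the recovered reads, 8 functional and 6 marker lists passed.

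Genes were named by a rule fixed before the data were examined. It took the 12 genes per direction with the largest log2 change among calls with a CPM of at least 5 in the higher group and no overlap of the groups. Predicted genes, clone names, pseudogenes and immunoglobulin and T cell receptor segments were left out. It also took up to 4 members of smallest p per list, of which 3 or 4 are given for lists that passed and at least 1 for the others, and Adgre1, Ptprc, Csf1r and Itgam. Some genes that this rule took are not reported here. Genes whose exons overlapped another gene on the same strand over at least 10% of their length were marked, and 12 of the 381 called genes were among them.

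The scripts were tested on data simulated from the real means and library sizes for KO against WT, with 3 and 3 libraries and 15619 genes. limma recovered 24%, 76%, 88% and 94% of 50 genes changed by 1, 2, 3 and 4 on the log2 scale, and called 6 of 15419 unchanged genes. In a simulation with 1 list moved by 1, camera called that list and 0 of the 41 others. Genes were drawn independently there, while correlations estimated from the 6 libraries reached 0.934, for the B cell list. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Precision is limited by 3 libraries per group, with 10790842 to 22157238 reads each, and a log2 change of 1 was mostly missed at this size.

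Alternatives fixed before the data were examined were, for genes, edgeR with DESeq2-style factors or total library size, DESeq2, limma-voom and robust edgeR. For genes and lists they were no low-count filter and a filter of a CPM of at least 1 in 3 libraries. A replicate block and leaving out each library were also used for both. The lists were further tested with DESeq2-style factors, an estimated inter-gene correlation and fry. While camera tests a list against all other genes, fry tests it against no change. Alternatives added after seeing the data were edgeR for the genes and voom for the lists, the tests first fixed, on the recovered reads. Pseudocounts of 0.5 and 5, TMM factors in limma and the sum of a gene's transcripts were also chosen then. So were removal of overlapping genes and leaving out WT replicate 3 and KO replicate 1 together. The work used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.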

Results

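The study profiled liver cells of male C57BL/6 mice, 3 months old, that carried the surface antigen F4/80, a marker of mouse macrophages. All animals had been given carbon tetrachloride (CCl4) by intraperitoneal injection, a hepatotoxin that injures hepatocytes and leads to fibrosis on repeated dosing. The livers were digested and the F4/80-positive cells were collected on magnetic columns. Polyadenylated RNA of these cells was sequenced with a strand-specific kit. There were 3 libraries from wild-type (WT) and 3 from knockout (KO) mice, and genotype was the only label that differed between the groups. The labels did not say that each library came from a separate animal, so the p-values measure the spread between these samples. With 1 transcript kept per gene, the WT libraries held 15027644, 16600429 and 22157238 reads and the KO libraries held 10790842, 12818227 and 19163317. Mitochondrially encoded transcripts took 16.7% ± 10.6 (SD, n = 3) of the WT reads and 17.5% ± 2.12 (SD, n = 3) of the KO reads. The WT libraries ranged from 6.19% in replicate 3, with a 95% Wilson interval of 6.18 to 6.20, to 27.5% in replicate 2. These intervals cover counting error only.

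The first question was how alike the 6 libraries were. Across the 15619 tested genes, Spearman correlations of log2 values averaged 0.965 over the 6 pairs of libraries of one genotype and 0.946 over the 9 pairs of different genotype. The ranges were 0.957 to 0.978 within and 0.928 to 0.958 between genotypes, so they overlapped slightly. These correlations are across genes, which are not independent replicates. The first principal component held 35.0% of the variance and parted the WT libraries, at scores of -49.1 to -40.3, from the KO libraries, at 31.8 to 53.3. The second component held 23.3% and set KO replicate 1, at -75.9, apart from the other libraries.

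The comparison of KO with WT asks how genotype alters the transcriptome of these cells after CCl4. The labels name no targeted gene, so no target level could be set against the group labels. Adgre1, which encodes F4/80 itself, stood at 6208 ± 1613 normalised counts in WT and 5254 ± 1233 in KO libraries (SD, n = 3 each; log2 change -0.23, SE 0.26, limma adjusted p = 0.706). Itgam, which encodes the integrin CD11b, had a log2 change of -0.09 (SE 0.31, limma adjusted p = 0.914). This gene shares exon sequence with the overlapping model Gm49368, so its count may hold reads of both. Ptprc, the pan-leukocyte antigen CD45, was at 24612 ± 6145 in WT and 12406 ± 3275 in KO libraries (log2 change -0.99, SE 0.30). Csf1r, the receptor for the macrophage growth factor CSF1, was at 32119 ± 7500 and 16689 ± 1352 (log2 change -0.92, SE 0.29). Neither Ptprc nor Csf1r passed, with limma adjusted p of 0.116 and 0.127. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in all 6 libraries, and Xist had at most 4 reads in any library.

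Lyz2, which encodes the macrophage lysozyme, fell more than any other gene in the KO libraries, from 89491 ± 23938 to 1335 ± 720 normalised counts (SD, n = 3 each). Its neighbour and paralog Lyz1, the lysozyme of Paneth cells, rose from 185 ± 71.3 to 4362 ± 2136. The genes with the highest log2 changes were Mup7, Elovl3 and Slco1a1, and Treml4, Adgre4 and Itga4 were among those that fell. Over all 15619 genes, 381 passed limma's test at an adjusted p under 0.05, of which 326 were higher and 55 lower in KO. At an unadjusted p under 0.05 there were 2810 genes. The 3 WT and 3 KO values of all 381 genes did not overlap. Among all tested genes the groups did not overlap for 3054, or 19.6%, where chance gives 10%.

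Lyz2 (ENSMUSG00000069516) lies on the minus strand of chromosome 10 at 117277331 to 117282321 in GRCm38, and Lyz1 (ENSMUSG00000069515) at 117287797 to 117292868 on the same strand. The log2 change of Lyz2 was -6.20 (SE 0.43, limma adjusted p = 0.00151), a 73.6-fold lower level on the scale of log2(value + 1). KO replicates 1, 2 and 3 held 587, 1394 and 2023 normalised counts, against 63752 in the lowest WT library. The log2 change of Lyz1 was 4.52 (SE 0.37, limma adjusted p = 0.0025), a 23.0-fold higher level. These paralogs are similar in sequence and the treatment of reads that match both is not given in the sources used here, so part of either count may belong to its paralog.

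Among the 12 largest increases, Mup7, one of the major urinary proteins, had 3 reads over the WT libraries and 818 over the KO libraries, a ratio of 375 with a counting interval of 128 to 1820. Slco1a1, an organic anion transporter, had 1 read in WT and 234 in KO, a ratio of 322 with an interval of 57.2 to 12800. Elovl3, a fatty acid elongase, rose from 3.45 ± 4.28 to 293 ± 173 (log2 change 6.44, SE 0.81, limma adjusted p = 0.0144). Serpina1e, an alpha-1-antitrypsin gene, rose from 704 ± 497 to 11803 ± 3183 (log2 change 4.49, SE 0.66). Car3, a carbonic anhydrase, rose from 594 ± 431 to 6648 ± 2342 (log2 change 3.70, SE 0.51). Slc25a47, a mitochondrial carrier of the liver, rose from 68.2 ± 9.01 to 836 ± 337 (log2 change 3.51, SE 0.34, limma adjusted p = 0.00452). Cyp4a12a, Etnppl, Keg1, Selenbp2 and Cyp8b1, the last an enzyme of bile acid synthesis, had log2 changes of 4.56, 3.73, 3.71, 3.52 and 3.49. Mup7 and Serpina1e belong to families of near-identical genes, so their counts are uncertain between family members.

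After Lyz2, the other large decreases were smaller. Tmc3 fell from 572 ± 302 to 97.5 ± 22.7 normalised counts (log2 change -2.37, SE 0.45, limma adjusted p = 0.0352) and Dnah12, a dynein heavy chain, from 307 ± 60.6 to 74.2 ± 45.9. Grk3, a kinase of G-protein-coupled receptors, fell from 4708 ± 1157 to 1311 ± 570 (log2 change -1.91, SE 0.32, limma adjusted p = 0.0225). Treml4 and Adgre4, surface receptors of myeloid cells, fell by 1.72 and 1.57 on the log2 scale. The guanine exchange factor gene Dock5 fell by 1.60, the chloride cotransporter gene Slc12a2 by 1.56, Tbc1d8 by 1.53 and Rap1gap2 by 1.51. Itga4, the alpha subunit of the integrin VLA-4, fell from 11811 ± 2999 to 4447 ± 1995.

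Single libraries carried much of the gene count. Without KO replicate 3, 8 genes passed and 3 of the 24 genes of largest change, Lyz2, Lyz1 and Slc25a47, kept their call, with limma adjusted p of 0.00111, 0.00518 and 0.0397. The counts were 138 without KO replicate 2, 174 without WT replicate 1, 210 without WT replicate 3 and 809 without KO replicate 1. On the recovered reads, edgeR's quasi-likelihood test called 282 genes, 220 higher and 62 lower, of which 266 were among the 381. Of 54 called genes that the naming rule took, edgeR's test did not call 15: Dnah12, Treml4, Itga4, Spp1, Cxcl1, Ccl24, Ifit3, Acads, Apoc1, Gsr, Cd59a, Emcn, Tie1, Dnase1l3 and Col1a1, with adjusted p of up to 0.0737 for Spp1. With the transcripts of a gene summed, 25 of the 54 lost their call.

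**Figure D1:**
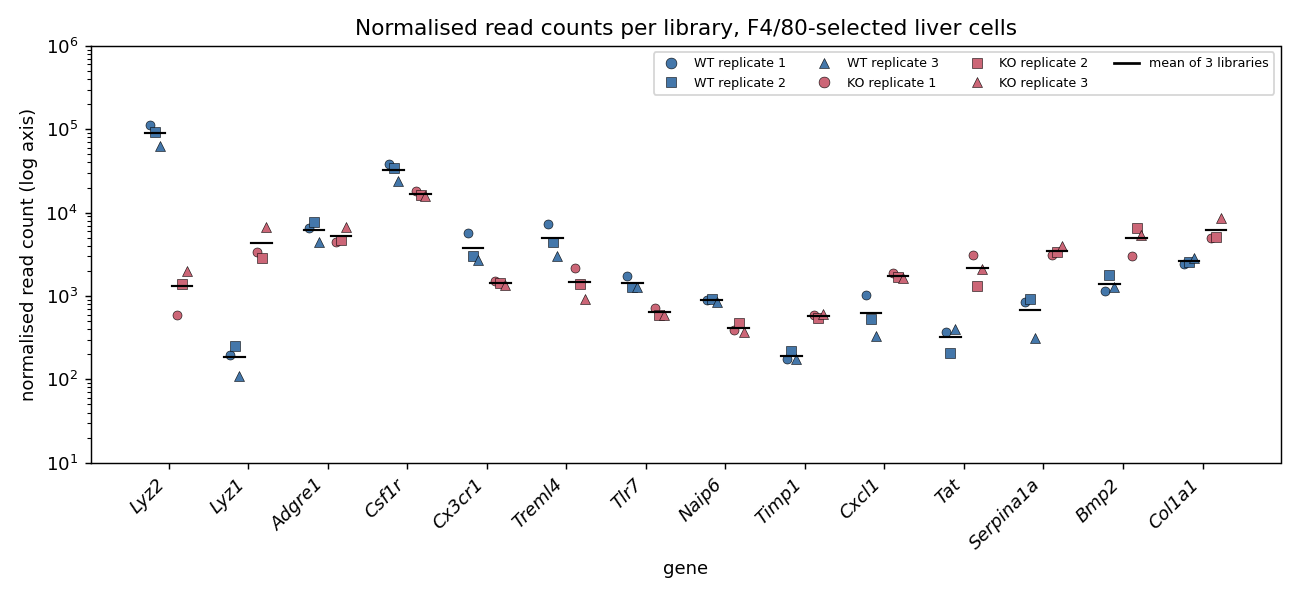
Normalised read counts (log axis) of 14 genes in each of the 3 WT and 3 KO libraries, with a bar at each group's mean. The KO values of Lyz2 lie at 587 to 2023 and the lowest WT value at 63752, while the WT and KO values of Adgre1 overlap.

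**Figure D2:**
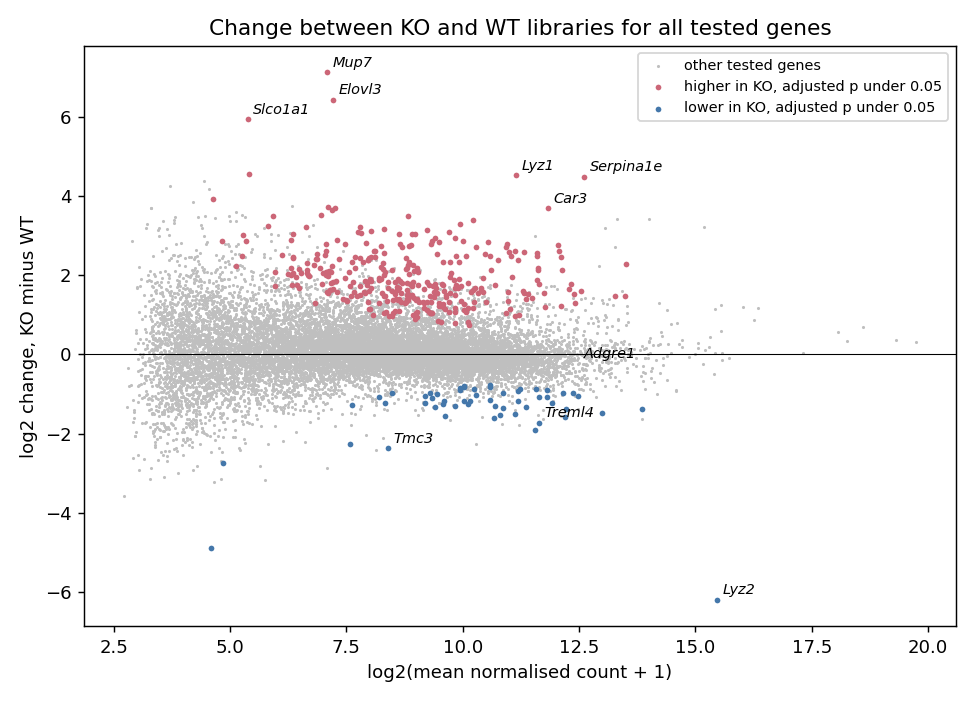
Log2 change, KO minus WT, of each of the 15619 tested genes against log2(mean normalised count + 1), with the 326 genes higher and 55 genes lower in KO at a limma adjusted p under 0.05 in colour. Lyz2 lies at -6.20, far below the other abundant genes, and Mup7, Elovl3 and Slco1a1 lie highest.

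Lists of genes fixed before the data were examined were tested beside these calls. Some lists that passed, such as cell cycle and NF-kB feedback, held no gene called over all genes. Of 27 functional lists, 8 passed camera's test of a list against all other genes with the preset correlation of 0.01. They were lower in KO for 5 lists and higher for 3. None kept its call when the correlation between genes was estimated from the 6 libraries.

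Lists of inflammasome, toll-like receptor and NF-kB feedback genes were lower in KO by camera's test with the preset correlation, and directional fry, which tests a list against no change, gave them adjusted p of 0.251, 0.251 and 0.65. Markers of hepatocytes and endothelium had median log2 changes of 1.73 and 1.42. In the inflammasome and lytic cell death list, 17 of 20 measured genes had a log2 change below 0 and 3 passed the gene test, as did 3 adjusted over the list alone (camera adjusted p = 1.3e-05). With an estimated correlation the adjusted p was 0.853. The 3 genes were Naip6, a sensor of bacterial flagellin, which fell from 885 ± 42.0 to 414 ± 56.3, Mefv, which encodes pyrin, from 981 ± 325 to 380 ± 62.0, and the inflammasome scaffold gene Nlrc4, from 399 ± 77.6 to 188 ± 22.7. Nlrc4 lost its call in each of the 6 fits without 1 library. Naip2 had a log2 change of -0.65 and did not pass. In the toll-like receptor signalling list, 2 of 29 genes fell over all genes and 7 adjusted over the list alone, where 1, Lbp, named after its value was seen, was higher (camera adjusted p = 3.1e-05, and 0.853 with an estimated correlation). Tlr7, a sensor of single-stranded RNA, fell from 1444 ± 268 to 638 ± 76.0 (log2 change -1.17, SE 0.19, limma adjusted p = 0.0219). Ticam2, an adaptor of TLR4, fell from 456 ± 114 to 190 ± 21.6, and overlaps Tmed7 on the same strand. Tlr1 and Tlr13, at -0.83 and -0.82, passed only adjusted over the list alone. The NF-kB feedback list was also lower, with 6 of 20 genes above 0 and a median log2 change of -0.42, although no member passed over all genes or adjusted over the list alone (camera adjusted p = 0.0014, and 0.853 with an estimated correlation). Its members of smallest p were Bcl3, Nfkb1, Traf1 and Tnip1, at -0.59, -0.54, -1.04 and -0.59. Without KO replicate 3 that list's adjusted p was 0.0942.

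The monocyte and cell cycle lists were also lower by camera's test with the preset correlation, while hepatocyte, endothelial and erythroid markers had median log2 changes of 1.73, 1.42 and 3.12. In the list of monocyte and recruited macrophage genes, 16 of 18 members were below 0, with a median log2 change of -0.45 (camera adjusted p = 0.000875, and 0.853 with an estimated correlation). Cx3cr1, the fractalkine receptor, fell from 3815 ± 1670 to 1431 ± 87.2 (log2 change -1.33, SE 0.27, limma adjusted p = 0.0433), the only member to pass over all genes and adjusted over the list alone. Ifitm6, Plac8 and Ccr2 had log2 changes of -0.74, -1.03 and -0.61. All 30 measured cell cycle genes were below 0, with a median of -0.36, and none passed over all genes or adjusted over the list alone (camera adjusted p = 3.5e-06, and 0.853 with an estimated correlation). Mki67, the proliferation antigen Ki-67, was at 913 ± 161 in WT and 397 ± 186 in KO libraries, Birc5 at a log2 change of -0.87, Ccnb2 at -1.12 and Kif11 at -0.88. Relative to the WT mean, the mean level of this list was -0.25 in KO replicate 1 and -0.30 in WT replicate 1, so the groups overlapped.

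Lists of oxidative metabolism and of interferon response were higher in KO by the same test. In the fatty acid oxidation list, 20 of 21 genes were above 0, 4 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 2.5e-07, and 0.853 with an estimated correlation). Acaa2, a thiolase of mitochondria, rose from 1284 ± 286 to 2832 ± 518 (log2 change 1.15, SE 0.22, limma adjusted p = 0.0346), Hadh from 535 ± 97.9 to 1128 ± 205 and Acads from 507 ± 43.7 to 914 ± 106. Acads lost its call in each of the 6 fits without 1 library. In the oxidative phosphorylation list, 30 of 32 genes were above 0 with a median of 0.24, and no member passed over all genes or adjusted over the list alone (camera adjusted p = 0.0151, and 0.993 with an estimated correlation). Ndufv1, Atp5d, Ndufb9 and Ndufa2 had log2 changes of 0.63, 0.69, 0.44 and 0.43. Hepatocytes express these genes strongly, and hepatocyte markers had a median log2 change of 1.73. In the type I interferon list, 21 of 28 genes were above 0, with a median of 0.46 (camera adjusted p = 0.0156, and 0.853 with an estimated correlation). Ifit3 alone passed, over all genes and adjusted over the list alone, and rose from 160 ± 35.3 to 354 ± 42.4 (limma adjusted p = 0.047). Ifit3 lost its call in each of the 6 fits without 1 library, at adjusted p of 0.0509 to 0.168, and edgeR's adjusted p was 0.0619. Bst2, Oasl2 and Ifi44 had log2 changes of 0.87, 0.57 and 1.10. Endothelial and stellate cell markers had median log2 changes of 1.42 and 0.66. The interferon call was lost without WT replicate 1, WT replicate 3 or KO replicate 1, and the oxidative phosphorylation call without WT replicate 3 or KO replicate 1, with camera adjusted p of up to 0.109 and 0.264.

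Markers of other liver cells were examined because the magnetic selection can retain them. Of 15 marker lists, 6 passed camera's test, 5 of them higher in KO. All 20 hepatocyte markers were above 0, 7 rose over all genes and 15 adjusted over the list alone (camera adjusted p = 1.8e-12, and 0.853 with an estimated correlation). Tat, a tyrosine-degrading enzyme, rose from 326 ± 107 to 2186 ± 906, Serpina1a from 689 ± 330 to 3492 ± 488, the cytochrome gene Cyp2e1, whose product activates CCl4, from 321 ± 122 to 1623 ± 573 and Mup3 from 1109 ± 601 to 7373 ± 3674. All 17 endothelial markers were above 0, 6 rose over all genes and 16 adjusted over the list alone, with a median of 1.42 (camera adjusted p = 1.4e-11, and 0.853 with an estimated correlation). Bmp2, a growth factor of sinusoidal endothelium, rose from 1405 ± 345 to 4963 ± 1751, and Emcn, Tie1 and Dnase1l3 had log2 changes of 1.45, 1.53 and 1.49.

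Of 18 stellate cell and myofibroblast markers, 16 were above 0, 1 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00192, and 0.853 with an estimated correlation). Col1a1, a chain of type I collagen, rose from 2597 ± 225 to 6246 ± 2115 (limma adjusted p = 0.0401), and Col1a2, Loxl1 and Bgn had log2 changes of 1.13, 1.11 and 0.98. The call of this list was lost without WT replicate 3, with an adjusted p of 0.191. Of 11 cholangiocyte markers, 10 were above 0, 1 rose over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0156, and 0.853 with an estimated correlation), and this call was lost without WT replicate 2, at 0.0756. Spp1, which encodes osteopontin and is also a gene of scar-associated macrophages, rose from 4320 ± 3105 to 18954 ± 8355. Krt8 and Krt18 had log2 changes of 1.28 and 0.92. All 8 measured erythroid genes were above 0, with a median log2 change of 3.12, none passed over all genes and 5 passed adjusted over the list alone (camera adjusted p = 0.000451, and 0.853 with an estimated correlation). Hba-a1 had 3231 ± 3492 normalised counts in WT and 29664 ± 26733 in KO libraries, and Hba-a2, Hbb-bs and Alas2 had log2 changes of 3.42, 3.21 and 3.00. Hba-a1 and Hba-a2 are near-identical copies whose counts cannot be told apart. Relative to the WT mean, the erythroid list was at 1.89 in WT replicate 2 and 1.25 in KO replicate 3, so the groups overlapped. The neutrophil list was lower, with 3 of 17 genes above 0 and 1, Retnlg, lower adjusted over the list alone and none over all genes (camera adjusted p = 0.0228, and 0.853 with an estimated correlation). Retnlg, Mmp8, Csf3r and Mmp9 had log2 changes of -1.17, -0.68, -0.48 and -0.49, and the list's call was lost without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3, with adjusted p of up to 0.162.

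**Figure D3:**
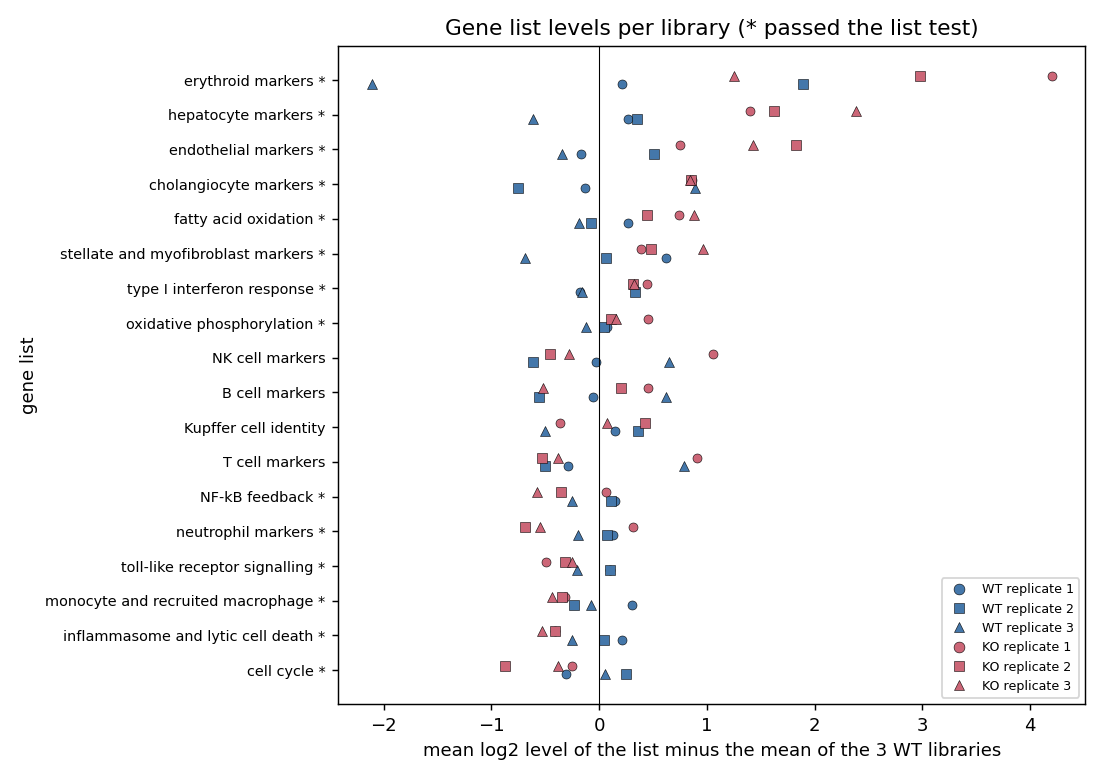
Mean log2 level of gene lists in each library, relative to the mean of the 3 WT libraries, for the 14 lists that passed camera's test and for 4 lists that did not. The KO libraries lie 1.40 to 2.39 above the WT mean for hepatocyte markers and 0.75 to 1.83 above it for endothelial markers. WT and KO libraries overlap for Kupffer cell, T cell, B cell and NK cell genes. Among lists that passed, they also overlap for cell cycle, NF-kB feedback, interferon, stellate cell, cholangiocyte, neutrophil and erythroid genes.

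Apart from the monocyte and recruited macrophage list, the lists that define macrophage states did not pass as groups. The Kupffer cell identity list had a median log2 change of 0.09 (camera adjusted p = 0.851), no member passed over all genes, and 1 was higher and 2 lower adjusted over the list alone. Clec4f, a lectin of resident Kupffer cells, was at 3190 ± 72.9 in WT and 7182 ± 2322 in KO libraries (log2 change 1.12, limma adjusted p = 0.0537), while Spic was at -1.52 and the scavenger receptor gene Marco at -1.63. Among 18 scar-associated macrophage genes, Spp1 rose over all genes and adjusted over the list alone and the list had an adjusted p of 0.27. Cd36 was at 0.88. Among 22 matrix protease and inhibitor genes, Timp1, an inhibitor of metalloproteinases, rose from 190 ± 25.6 to 583 ± 33.4 (log2 change 1.62, SE 0.20, limma adjusted p = 0.0144), 5 were higher adjusted over the list alone, and the list had a camera adjusted p of 0.343. Of 17 profibrogenic ligands none passed over all genes and 3, Tnfsf12, Ccn2 and Vegfa, were higher adjusted over the list alone, at 0.78, 0.88 and 0.83 (camera adjusted p = 0.145). Tnfsf12 overlaps the read-through model Tnfsfm13. Of 26 cytokine and chemokine genes 2 rose over all genes and adjusted over the list alone, the neutrophil chemoattractants Cxcl1, from 626 ± 351 to 1751 ± 142, and Cxcl3, from 30.0 ± 7.67 to 131 ± 42.8 (camera adjusted p = 0.75). In the alternative activation list Ccl24 rose from 86.7 ± 68.3 to 461 ± 165, and adjusted over the list alone 2, Ccl24 and Arg1, were higher and 1, Pdcd1lg2 at -1.78, lower (camera adjusted p = 0.806).

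Among lists of lipid metabolism and stress, single members changed without the list. In the eicosanoid and endocannabinoid list Ephx2, the soluble epoxide hydrolase, rose from 221 ± 183 to 1746 ± 593 (limma adjusted p = 0.0267), adjusted over the list alone 7 were higher and 1 lower, and the camera adjusted p was 0.133. Mgll was at 1.22 and the lower gene, Hpgds, at -1.27. In the list of LXR targets and cholesterol efflux Apoc1 rose from 2156 ± 622 to 4842 ± 821, and adjusted over the list alone 1 was higher and 1, Scd2 at -0.83, lower (camera adjusted p = 0.766). In the NRF2 list Gclm, a subunit of the glutathione-synthesising ligase, rose from 403 ± 79.4 to 838 ± 106, and the glutathione reductase gene Gsr fell from 4295 ± 822 to 2073 ± 510. Adjusted over the list alone 6 of its 21 genes were higher and 2, Gsr and G6pdx, the latter named after its value was seen, lower (camera adjusted p = 0.807). In the complement list Cd59a rose from 244 ± 65.4 to 646 ± 173, the 1 member to pass over all genes and adjusted over the list alone, and Cd55 was at 0.64 (camera adjusted p = 0.145). No member passed over all genes in the lists of glycolysis and hypoxia, of efferocytosis and scavenger receptors, of lysosome, autophagy, unfolded protein response, cholesterol synthesis, MHC class II, immediate early or ribosomal protein genes. Adjusted over the list alone, 3 glycolysis and hypoxia genes were higher and 1 lower, 1 efferocytosis gene was higher and 3 were lower, and the counts were 0 in the other 7 lists. The camera adjusted p of these 9 lists, in the order named, were 0.343, 0.766, 0.807, 0.807, 0.618, 0.302, 0.418, 0.437 and 0.807. Among the members of smallest p were Bnip3 at 1.17 and Pfkfb3 at -0.57, Itgb3 at -0.85 and Elmo1 at -0.83, Ctsc at -0.90 and Ctsl at 0.87, Gabarapl1 at 0.90 and Optn at 0.93, Edem1 at -0.57 and Asns at 0.85, Tm7sf2 at 0.68, Cd40 at -0.76 and Ciita at -0.52, Klf2 at 0.94 and Dnajb1 at 0.53, and Rpl27 at 0.95 and Rps14 at 0.32. Tm7sf2 overlaps Vps51 on the same strand.

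The other marker lists gave no call. The medians of T cell, NK cell and B cell markers were -0.01, 0.21 and 0.05, with camera adjusted p of 0.807, 0.952 and 0.807, and no member passed over all genes or adjusted over the list alone. Cd28 and Trbc1 were at -1.07 and 0.53, Eomes and Klrk1 at -0.81 and 0.25, and Fcer2a and Cr2 at 0.33 and -0.25. Lymphocyte markers were highest in KO replicate 1 and WT replicate 3, at 0.91 and 0.79 above the WT mean for the T cell list. Plasma cell, plasmacytoid dendritic cell, eosinophil and platelet markers also had 0 members past either threshold, with camera adjusted p of 0.807, 0.375, 0.165 and 0.624. Sdc1 and Irf4 were at 0.54 and 0.48, Runx2 and Ccr9 at -1.07 and -0.55, Siglecf and Ear2 at -1.03 and -1.01, and Pf4 and Gp1ba at 0.70 and -0.70. Of the dendritic cell list 4 members, Zbtb46, Kit, Fscn1 and Dpp4, were higher adjusted over the list alone and 0 over all genes, at 1.30, 0.86, 1.04 and 0.81 (camera adjusted p = 0.993). Of the mast cell and basophil list 2, Kit and Gata2, were higher adjusted over the list alone, Gata2 at 0.96 (camera adjusted p = 0.485). The direction of the list test and the median differed for the lysosome, efferocytosis, B cell, autophagy and dendritic cell lists, whose medians were 0.02, 0.04, 0.05, -0.01 and -0.21.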

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

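The number of calls moved with the setting. All shared calls kept their direction under every setting, but a call shared by fits of the same libraries could hardly reverse. Chosen after seeing the data were both pseudocounts, TMM factors in limma, summed transcripts, removal of overlapping genes and 2 against 2 libraries. The tests first fixed, edgeR for the genes and voom for the lists, were added on the recovered reads as alternatives. The 381 calls (326 higher, 55 lower) became 1321 (927, 394) with DESeq2, which kept all 381, 233 (205, 28) with summed transcripts and 701 (475, 226) with 2 against 2 libraries. The lower count alone moved to 36 with no low-count filter and to 112 in edgeR with total library size. That last setting changed both the test and the scaling: edgeR with TMM factors gave 62 lower genes. Leaving out 1 library gave 8 to 809 calls, 7 to 640 higher and 1 to 169 lower. Simulated log2 changes of 1 were mostly missed with 3 libraries per group, and depth was not varied. The cause of these shifts was not tested.

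Same-numbered WT and KO libraries had correlations of deviations of -0.015, 0.088 and -0.142. The labels state no pairing, and with 3 libraries per group these correlations can neither show nor exclude one. A replicate block, which gave 539 calls (452 higher, 87 lower), is therefore only a setting. Of the 8 functional and 6 marker lists, an estimated correlation kept 0 of each. fry tests a list against no change rather than against other genes: over all lists the directional form called 0 and the mixed form called 5 functional and 1 marker list, of which the inflammasome, toll-like receptor and hepatocyte lists were among those 14. Leaving out 1 library gave 8 to 14 functional and 4 to 7 marker lists. The similarity difference of 0.0191 became 0.172 over the 500 most variable genes.

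Directions reversed only for genes and lists that did not pass. Without 1 library each, log2 changes ranged from -0.40 to 0.15 for Itgam, -0.00905 to 0.91 for Trbc1, -0.0488 to 0.53 for Klrk1, -0.0466 to 0.71 for Fcer2a and -0.54 to 0.10 for Cr2, which was at 0.0200 with 2 against 2 libraries. 
For the lists that reversed, the adjusted p without 1 library each was, for Kupffer cell identity 0.0874 to 0.975, scar-associated macrophage 0.00309 to 0.975, inflammatory cytokines and chemokines 0.109 to 0.686, alternative activation 0.248 to 0.991, LXR and cholesterol efflux 0.336 to 0.991, autophagy 0.657 to 0.987, lysosome 0.0103 to 0.97, NRF2 response 0.277 to 0.975, efferocytosis and scavenger receptors 0.0203 to 0.82, complement 0.0125 to 0.955, ribosomal proteins 0.0191 to 0.943, T cell 0.0129 to 0.657, NK cell 0.0868 to 0.941, B cell 0.0535 to 0.719, plasma cell 0.143 to 0.959, dendritic cell 0.447 to 0.97, plasmacytoid dendritic cell 0.043 to 0.991, mast cell and basophil 0.0103 to 0.996 and platelet and megakaryocyte 0.00188 to 0.719. With 2 against 2 libraries the reversed lists were at inflammatory cytokines and chemokines 0.565, autophagy 0.968, NRF2 response 0.361, ribosomal proteins 0.232, NK cell 0.8005, B cell 0.672 and plasma cell 0.732. With no low-count filter the reversed lists were at lysosome 0.988. With directional fry the reversed lists were at lysosome 0.988, T cell 0.988 and B cell 0.988. Mixed fry, which has no direction, gave the lysosome, T cell and B cell lists adjusted p of 0.549, 0.854 and 0.855. With voom the reversed lists were at NK cell 0.877 and platelet and megakaryocyte 0.957. With the CPM filter the reversed lists were at dendritic cell 0.983.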

Other observations

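The following tests were chosen after the results were seen, except those of centred hepatocyte markers, of unseen male-biased and non-classical monocyte genes, and of length and GC content. The gene lists in this part were written from general knowledge after the calls had been examined. Genes of amino acid breakdown, which hepatocytes express, were higher in KO alongside the hepatocyte markers, of which 20 of 20 were above 0 at a median log2 change of 1.73, and no enrichment of these lists was tested. All 6 measured genes of phenylalanine and tyrosine degradation rose, at log2 changes of 2.06 to 2.78, among them Hpd, from 498 ± 244 to 3435 ± 1686 normalised counts (SD, n = 3 each), and Fah, from 276 ± 98.6 to 1582 ± 650. All 4 genes of histidine degradation rose, led by Amdhd1 at 3.18 and Hal at 2.93. Of 9 genes of methionine and cysteine metabolism 8 rose, with Cbs, the first enzyme of transsulfuration, at 124 ± 46.7 in WT and 1079 ± 278 in KO (limma adjusted p = 0.0057) and Bhmt, at 1.87, missing the threshold. Of 6 urea cycle genes Cps1, Otc and Ass1 rose, while Asl, Arg1 and Nags were at 1.03, 1.24 and 3.03 and did not pass.

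Non-classical monocytes patrol vessels and express the genes Cx3cr1, Treml4, Adgre4, Itgal and Pou2f2. Itgal fell from 21193 ± 4705 to 8359 ± 2711 normalised counts and Pou2f2 from 2692 ± 169 to 1065 ± 212. A further 8 textbook genes of these cells, whose values had not been examined, were all below 0: 0 passed over all genes and 7 passed adjusted over the list alone. Spn was at 6503 ± 2160 in WT and 2323 ± 1125 in KO, Cd300e at a log2 change of -1.79 and Eno3 at -1.75. Ace, at -1.39, was in this list when the test was first run and was moved out after the result, because its direction had been noted before. With Ace put back the median of the 9 genes was -1.39. Ptprc and Csf1r, genes of leukocytes and macrophages in general, were at -0.99 and -0.92, and hepatocyte, endothelial and erythroid markers had medians of 1.73, 1.42 and 3.12, so the fall may not be specific to these cells.

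The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split called 381 genes and the highest of the other splits 0, so 1 of the 10 splits called as many. For the gene lists the real split called 14 and the highest of the others 26, and 8 of the 10 splits called as many. What gave the list calls of the other splits was not tested.

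Of the 20 hepatocyte markers 7 rose over all genes, and the list passed camera's test only with the preset correlation (adjusted p 0.853 with an estimated one). Alb was at 43193 ± 22321 in WT and 89521 ± 25893 in KO libraries and did not pass (limma adjusted p = 0.283). A candidate explanation is that more hepatocyte RNA was carried through the F4/80 selection, at one higher share: after centring each library on the mean of the 20 markers, none of which another list holds, 1 marker, Trf, still differed between groups (limma adjusted p over the list = 0.0132), where 2 or more had been set as the bound against it. The centred log2 changes ran from -1.34 for Cyp3a11 to 1.03 for Pck1, with SE of up to 0.81, so this test was too weak to decide and the explanation stays open. Several of the largest increases, such as Mup7, Elovl3 and Slco1a1, are known to be higher in livers of males. Of 13 further male-biased genes, 6 were measured. Their median log2 change lay 0.0513 above that of the hepatocyte markers (permutation p = 0.913). The permutation was over genes, which are not independent replicates, and its result does not show that they did not differ. The 7 male-biased genes named in the results rose by a median log2 change of 4.56, from 3.52 to 7.13, against a median of 1.73 and a highest value of 2.83, that of Pck1, for the 20 hepatocyte markers. These 7 genes had been chosen by the size of their change, and whether that choice gives the gap was not tested. For the male-biased genes, one higher share of hepatocyte RNA therefore stays open, and no value measures that share. WT libraries from females are argued against by the Y-linked genes, whose lowest WT value was 239 normalised counts. A change of expression within hepatocytes, for Serpina1e for example, stays open as a hypothesis and was not tested.

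The near loss of Lyz2 with higher Lyz1 was the clearest single-gene pattern. Reads shared between these paralogs are argued against as the whole cause, since Lyz1 rose by a log2 change of 4.52 where loss of shared reads would lower it. Fewer macrophages are argued against as the whole cause by Adgre1, the gene of the selection antigen, whose log2 change lay 5.97 above that of Lyz2 (SE 0.50). Csf1r and Ptprc were at -0.92 and -0.99, so a smaller share of macrophage RNA is not excluded. As a hypothesis, the KO animals may carry an insertion at the Lyz2 locus, as lines that express Cre recombinase from this locus do: the KO level was 1.49% of the WT level, and at most 2.26% in any KO library. No deposited value reads an insertion and the labels name neither a Cre line nor a target, so this cannot be told apart from another loss of Lyz2 expression.

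The 55 lower genes, which were not assigned to cell types, could reflect the other RNA in the KO libraries, biased read recovery, or fewer cells of one kind. One dilution of all myeloid RNA cannot alone give the fall of Lyz2, which lay 5.97 below Adgre1 (SE 0.50), and stays open for the others. The mean of the Kupffer cell list differed by 0.042 (SE 0.35), where the least changed of the 55 lower genes was at -0.77, but the list holds 5 genes that endothelial cells also express, Cdh5, Lyve1, Id1, Id3 and Clec1b, and without them the mean differed by -0.16 (SE 0.34), too wide a spread to part it from -0.77. Ptprc and Csf1r, at -0.99 and -0.92, and Spic and Marco, at -1.52 and -1.63, went with a dilution. Clec4f at 1.12, Adgre1 at -0.23 (SE 0.26) and Itgam at -0.09 did not. The medians of scar-associated macrophage, lysosome and MHC class II genes were 0.26, 0.02 and -0.02. Genes that other cells also express were not removed from these lists, so their medians cannot decide. Length or GC content bias as the whole cause is argued against because 49 of the 55 genes stayed lower past the threshold once these trends were removed from each library, although the removal left 267 genes higher and 165 lower, against 326 and 55 before, and the 55 genes were longer, with a median of 5195 bases against 2792 for all tested genes. Fewer non-classical monocytes in the KO libraries is a hypothesis that the 8 unexamined genes are consistent with, at a median log2 change of -1.20, and a dilution stays open for these genes too. Lower expression per cell was not tested and stays open, as does genotype itself.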
